A study of Homo sapiens with 6 samples.

How the data were processed

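The data were poly(A)-selected RNA sequencing libraries of Mono-Mac-6 cells, a human MLL-AF9 leukaemia line, with 2 libraries for each of 3 groups and 6 in all: the control guide sgNS and the METTL1 guides sgMETTL1.3 and sgMETTL1.6. Per the labels' protocols, a Cas9 single clone was transduced by lentivirus, selected with blasticidin (10 µg/ml) and hygromycin B (200 µg/ml) and harvested 8 to 10 days after transduction. RNA was extracted with TRIzol per the protocol and with QIAzol per the design text, and libraries were made with a stranded mRNA kit. Per the submitters' processing notes, RSEM 1.2.31 and GRCh38 were used; the aligner and the gene annotation are not given in the sources used here. The authors deposited TPM, relative transcript levels that RSEM estimates from reads and transcript lengths, in 1 table with 18806 gene symbols. RSEM shares reads between similar transcripts by a model, so values of near-identical genes can trade places. Each library is scaled to the same total, so a change in abundant genes shifts all others, and TPM keeps no depth: the depth of each library is unknown and no counting interval can be given. The 6 value columns were matched to samples by name, and 0 columns of per-sample values were left unmapped. Every column name also carries the letters EV, whose meaning the labels do not give.

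Values were analysed as log2(TPM + 1) in R 4.3.3 with limma 3.58.1. Genes with a mean of at least 1 TPM over all libraries were kept, which left 10911. All 3 groups entered 1 linear model, with empirical Bayes moderation and a trend on mean level (3 residual and 9.84 prior degrees of freedom). The contrasts were the mean of both METTL1 guides against sgNS, each guide against sgNS, and sgMETTL1.6 against sgMETTL1.3. Benjamini-Hochberg adjusted p-values under 0.05 were called. Fold changes are on the log2(TPM + 1) scale, which understates the change of low genes. With 2 libraries in a group, no outlier test was made. Splits of the samples into guide and control libraries were counted only in the exact permutation test of METTL1. The control libraries were also split between the guides, a step chosen after seeing the data.

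Of 35 gene lists fixed before the data were examined, 30 had at least 5 tested members. They held 1084 different genes, of which 1042 were in the table, 76 under an older symbol. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the residuals, and with fry. The text names METTL1 and WDR4; the 12 highest rises and 12 deepest falls over both guides with every guide library on one side of both controls; the 3 members with the lowest p of each list past camera and 2 of each other list; the METTL1 neighbours that passed; and the 5 highest and lowest changes of each other contrast. Some genes that this rule or a list would name are not reported here. Positions were taken from GENCODE 29 on GRCh38, in which 18294 symbols had a position; this copy may differ from the annotation the authors used. The overlap of the guides' calls was set beside 100 simulations in which all 3 groups, controls included, were drawn unchanged. Both simulated guides were compared with the same simulated controls.

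On simulated data with known changes, the comparison of both guides with control was run on 10911 genes. It recovered 76.1% of 67 genes changed 1.2-fold, 98.5% of 67 changed 1.5-fold and 100% of 66 changed 2-fold. It called 12 of 10680 unchanged genes. Noise was drawn there independently for each gene and library, with the spread estimated by the model. A deviation shared by the libraries of a group could not arise, so these rates may not hold for the real data. Alternatives were other pseudocounts, other filters on low values, quantile and median-ratio scaling, rescaling without ribosomal protein genes, limma without the trend, the replicate number as a block, other set tests and leaving out each library. Mitochondrially encoded mRNAs are not analysed here, since none of the list's members had a row in the table used.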

Results

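Transcript levels were measured by stranded poly(A) RNA sequencing in Mono-Mac-6, a human acute myeloid leukaemia line of monocytic type that carries the MLL-AF9 fusion. A single clone of this line that makes Cas9 received, by lentivirus, a control guide RNA (sgNS) or 1 of 2 guides against METTL1 (sgMETTL1.3 and sgMETTL1.6). METTL1 is the catalytic subunit of the enzyme that places N7-methylguanosine on tRNAs, and WDR4 is its partner subunit. Cells were harvested 8 to 10 days after transduction. There were 2 libraries per group and 6 in all. The deposited values were TPM, the estimated share of all transcripts scaled to the same total in each library, for 18806 gene symbols, and 10911 genes with a mean of at least 1 TPM were tested. TPM keeps no read depth, so the depth of each library is unknown and no counting interval is given. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Replicates differed by a median of 2.42% (sgNS), 2.44% (sgMETTL1.3) and 3.15% (sgMETTL1.6) over the 1742 genes with at least 100 TPM. The first principal component, with 75.4% of the variance, separated the control libraries from the 4 guide libraries, and the second, with 14.5%, separated the guides.

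The targeted gene was examined first. METTL1 (ENSG00000037897.16, minus strand of chromosome 12, 57768471 to 57772793 in GRCh38) stood at 14.6 ± 1.05 TPM in the sgNS libraries (SD, n = 2), 17.4 ± 1.22 TPM in those labelled sgMETTL1.3 and 11.4 ± 0.38 TPM in those labelled sgMETTL1.6. The single libraries held 15.38 and 13.89 TPM, 18.29 and 16.56 TPM, and 11.15 and 11.69 TPM in the same order. METTL1 mRNA was higher than control by a log2 change of 0.24 in the libraries labelled sgMETTL1.3 (limma, adjusted p = 0.011) and lower by a log2 change of -0.33 in those labelled sgMETTL1.6 (adjusted p = 0.0017). The rise did not pass the test without sgNS replicate 2, without sgMETTL1.3 replicate 1 (adjusted p = 0.116 each) or with no filter on low values (adjusted p = 0.057). Over both guides the log2 change was -0.05 (adjusted p = 0.53), and it was 0.02 without sgNS replicate 1. An exact two-sided permutation test of the 4 guide libraries against the 2 control libraries gave p = 1. Its 15 splits allow no one-sided p below 0.0667. A Cas9 cut leaves small insertions or deletions that gene-level TPM does not read, so these values check neither the cut nor the protein. The libraries labelled sgMETTL1.3 showed no loss of METTL1 mRNA. The submitters state that loss of the protein was checked by western blot, which is not used here. Every direction given for a guide is drawn from the libraries as labelled. WDR4 (ENSG00000160193.11, chromosome 21, 42843094 to 42879568) rose with both guides, from 23.8 ± 3.30 TPM to 35.5 ± 0.12 and 32.5 ± 2.62 TPM (SD, n = 2), a log2 change of 0.50 ± 0.068 (SE, adjusted p = 3.4e-05).

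**Figure D1:**
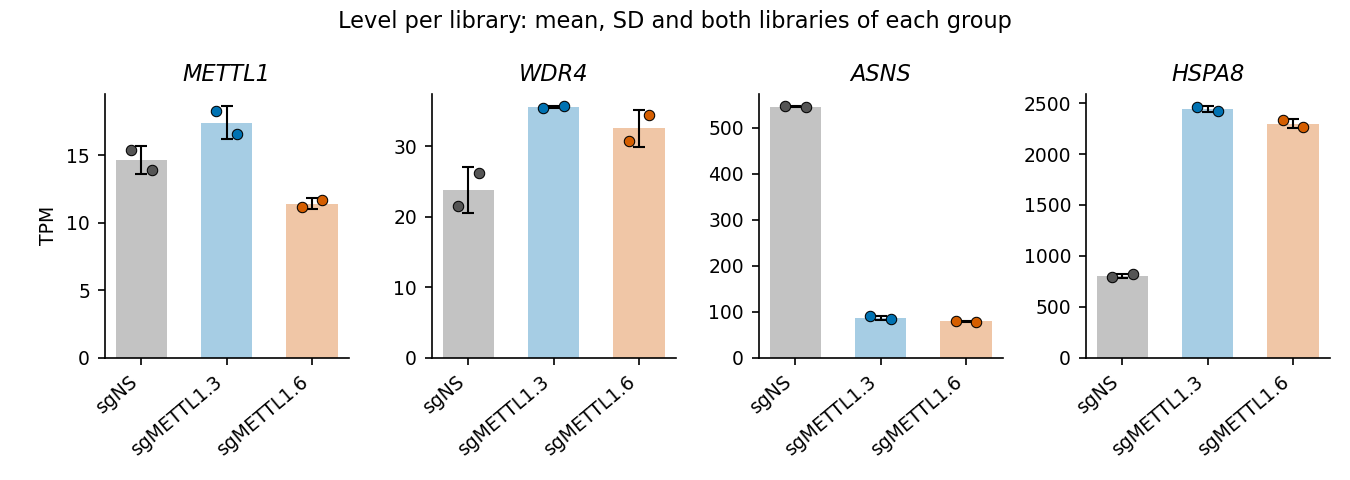
TPM of METTL1, WDR4, ASNS and HSPA8 in the sgNS, sgMETTL1.3 and sgMETTL1.6 libraries; bars are means, error bars the SD and points the 2 libraries of each group. METTL1 is at 17.4 TPM in the libraries labelled sgMETTL1.3 and 14.6 TPM in the controls, while ASNS falls from 546 TPM to 86.3 and 78.5 TPM.

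The main comparison asked which transcripts differ between the libraries of both METTL1 guides and the control libraries. Genes of the integrated stress response were lower and heat shock chaperones were higher, with smaller shifts across mitochondrial, ribosomal, interferon and myeloid genes. Of the 10911 genes, 6484 passed the test (limma, adjusted p under 0.05), 3556 of them higher and 2928 lower. The majority turned with median-ratio scaling (3133 higher, 3251 lower) and without ribosomal protein genes (3082 and 3242). Most changes were small. A log2 change of at least 1 was reached by 14 genes that rose and 145 that fell, and one of at least 0.5 by 320 and 593. Of the 30 gene lists tested with camera, 16 passed, 7 higher and 9 lower. None passed with the correlation between genes estimated from the residuals, and that p is given with each list that passed. Estimating it also leaves camera only the 3 residual degrees of freedom. Calls were lost too where the estimate lay below the preset 0.01, as for proteasome (-0.022) and monocyte and macrophage genes (-0.012). The loss of a call is therefore not due to that correlation alone. Members that go against their list, and marker genes of other cell types, were chosen after their values were seen. Gene list counts are of genes past the adjusted p over all genes tested, followed where stated by the count adjusted over the list alone.

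The integrated stress response list, the targets of ATF4 and its relatives that cells switch on when the initiation factor eIF2 is phosphorylated, had the lowest median of the 30 lists. Of its 36 tested members 35 fell and 1 rose, also when adjusted over the list alone, with a median log2 change of -1.76 (camera, adjusted p = 5.1e-32 and adjusted p = 0.111 with an estimated correlation). CHAC1 (chromosome 15, 40952962 to 40956519), which degrades glutathione, fell from 91.6 ± 3.97 TPM in the controls to 6.76 ± 0.0495 TPM with sgMETTL1.3 and 4.52 ± 1.02 TPM with sgMETTL1.6 (SD, n = 2), a log2 change of -3.83 ± 0.083 (SE, adjusted p = 6.1e-13). Enzymes of amino acid synthesis on the list fell too. ASNS (chromosome 7, 97852118 to 97872542), the asparagine synthetase, went from 546 ± 1.42 TPM to 86.3 ± 4.55 and 78.5 ± 1.46 TPM (log2 -2.71, adjusted p = 9.2e-15). PSAT1 and PHGDH, which act in serine synthesis, fell from 649 ± 11.8 to 102 ± 0.219 and 91.5 ± 2.06 TPM (log2 -2.73, adjusted p = 2.5e-15) and from 417 ± 12.3 to 79.3 ± 0.474 and 83.9 ± 2.19 TPM (log2 -2.34, adjusted p = 1.8e-14). CTH, which makes cysteine from cystathionine, had a log2 change of -3.0, the mitochondrial folate enzyme ALDH1L2 one of -2.72, SESN2 one of -2.54, and the secreted factors STC2 and INHBE ones of -2.52 and -2.50. PCK2, the mitochondrial form of phosphoenolpyruvate carboxykinase, which was not on the list, had a log2 change of -2.64. Of the transcription factors of the response, chosen after their values were seen, ATF4 fell from 606 ± 2.69 to 415 ± 4.89 and 396 ± 8.18 TPM (log2 -0.58) and DDIT3 from 128 ± 0.58 to 56.3 ± 2.16 and 46.5 ± 0.933 TPM (log2 -1.31). The member that rose was SESN3 (log2 1.01, adjusted p = 3.4e-09).

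Aminoacyl-tRNA synthetases, which charge tRNAs, fell as a list (23 tested, 15 lower and 5 higher, the same counts adjusted over the list alone, median log2 -0.75, camera adjusted p = 1.6e-06 and adjusted p = 0.162 with an estimated correlation). WARS fell from 532 ± 7.21 to 135 ± 5.15 and 113 ± 4.50 TPM (log2 -2.10), GARS had a log2 change of -1.67 and SARS one of -1.45. Those that rose were FARSA (0.47), RARS (0.34), KARS (0.21), AIMP2 (0.18) and VARS (0.16). The tRNA modification list rose slightly (56 tested, 27 higher and 8 lower, 28 and 8 adjusted over the list alone, median log2 0.12, camera adjusted p = 0.019 and adjusted p = 0.331 with an estimated correlation). PUS7, a pseudouridine synthase, rose by 0.53, the Elongator subunit IKBKAP by 0.43 and HSD17B10 by 0.34. Against the list, ADAT2 (-0.21), PUS10 (-0.20), PUS1 (-0.19), TRMT10A (-0.17), MTO1 (-0.16), ELP5 (-0.15), ELP3 (-0.15) and NAT10 (-0.15) fell. Translation factors moved both ways (15 higher and 16 lower of 40, camera adjusted p = 0.39). Among them EIF4EBP1, a translation repressor that is also on the stress list, fell from 771 ± 6.89 to 269.5 ± 2.72 and 261 ± 5.68 TPM (log2 -1.54) and EIF5 rose (log2 0.71).

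Heat shock chaperones rose (17 of 19 higher and none lower, also adjusted over the list alone, median log2 0.60, camera adjusted p = 1.9e-10 and adjusted p = 0.111 with an estimated correlation). HSPA8 (chromosome 11, 123057489 to 123063230), the constitutive HSP70, rose from 806 ± 20.1 to 2445 ± 26.7 and 2299 ± 44.9 TPM, a log2 change of 1.56 ± 0.024 (SE, adjusted p = 3.0e-14). HSPH1 rose by a log2 change of 1.2, HSPE1, the mitochondrial HSP10, by 0.87 and HSP90AA1 by 0.83. Proteasome subunits rose (31 tested, 19 higher and 4 lower, the same adjusted over the list alone, median log2 0.16, camera adjusted p = 0.0017 and adjusted p = 0.125 with an estimated correlation). PSMB2 rose by 0.44, PSMD11 by 0.43 and PSMD2 by 0.33. Against the list, PSMA1 (-0.25), PSMA4 (-0.11), PSMD8 (-0.094) and PSMD14 (-0.078) fell. Nuclear-encoded subunits of oxidative phosphorylation rose (52 tested, 40 higher and 4 lower, 41 and 4 adjusted over the list alone, median log2 0.18, camera adjusted p = 2.0e-07 and adjusted p = 0.111 with an estimated correlation). Among them were the ATP synthase subunits ATP5G1 (0.47) and ATP5A1 (0.33) and the complex I subunit NDUFB10 (0.40). Those that fell included NDUFB5 (-0.18), UQCRC2 (-0.11) and NDUFS1 (-0.088). The endoplasmic reticulum unfolded protein response list went both ways (12 higher and 11 lower of 29, camera adjusted p = 0.55). HERPUD1 fell on it by a log2 change of -1.41 and XBP1 by -0.85.

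Ribosomal protein and chaperone genes have pseudogenes that can share their reads. Cytosolic ribosomal protein genes fell by a small step (76 tested, 59 lower and 1 higher, 61 and 1 adjusted over the list alone, median log2 -0.12, camera adjusted p = 1.9e-10 and adjusted p = 0.149 with an estimated correlation). These genes took 22.8% and 22.4% of the TPM in the sgNS libraries, 19.96% and 20.1% in those labelled sgMETTL1.3 and 21.9% in each labelled sgMETTL1.6. RPL31 fell by a log2 change of -0.29 and RPL4 by -0.23. RPS26 alone rose, from 528 ± 2.87 to 914 ± 9.16 and 938 ± 3.58 TPM (log2 0.81, adjusted p = 1.0e-11). It has near-identical copies in the genome that could share its reads, so its value is uncertain. The ribosome biogenesis and MYC target list rose (43 tested, 36 higher and 2 lower, also adjusted over the list alone, median log2 0.29, camera adjusted p = 7.6e-08 and adjusted p = 0.125 with an estimated correlation). SRM, the spermidine synthase, rose by a log2 change of 0.71, LTV1 by 0.44 and NOP56 by 0.38, and the members that fell were MYC itself (-0.29) and WDR12 (-0.29).

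**Figure D2:**
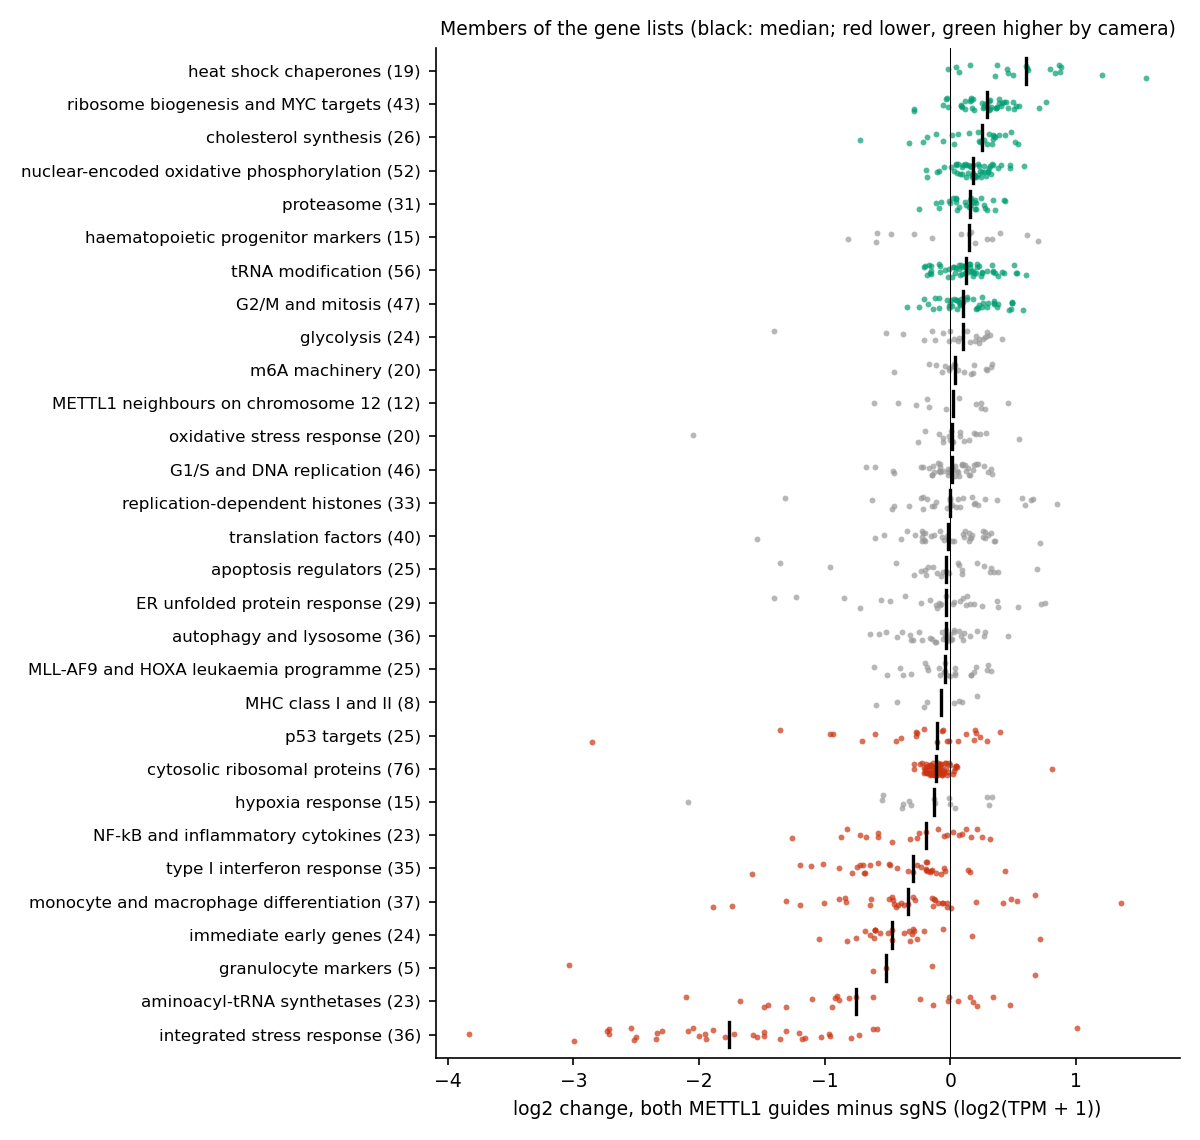
Log2 change on the log2(TPM + 1) scale, both METTL1 guides minus sgNS, of each tested member of the 30 gene lists (points; number of members in brackets), with the list median as a black line; red and green lists passed camera as lower and higher, grey ones did not. The integrated stress response list is farthest left with a median of -1.76 and the heat shock chaperones farthest right with a median of 0.60.

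The type I interferon response list fell (35 tested, 28 lower and 2 higher, 29 and 2 adjusted over the list alone, median log2 -0.30, camera adjusted p = 5.9e-08 and adjusted p = 0.111 with an estimated correlation). Its chemokine CXCL10 went from 17.2 ± 2.22 to 4.59 ± 0.417 and 5.60 ± 0.672 TPM (log2 -1.58), MX1 fell by a log2 change of -1.19 and XAF1 by -1.01. GBP4 (0.44) and BST2 (0.14) rose. Immediate early genes fell (24 tested, 20 lower and 2 higher, also adjusted over the list alone, median log2 -0.46, camera adjusted p = 1.0e-08 and adjusted p = 0.111 with an estimated correlation). IER3 fell by a log2 change of -0.82, DUSP1 by -0.75 and FOS by -0.64, and DUSP2 (0.71) and FOSL1 (0.17) rose. This list was fixed as a sign of handling too, and an effect of handling was not tested in any comparison. The NF-kB and inflammatory cytokine list fell (23 tested, 12 lower and 5 higher, the same adjusted over the list alone, median log2 -0.19, camera adjusted p = 0.012 and adjusted p = 0.169 with an estimated correlation). CXCL8 went from 160 ± 2.09 to 72.005 ± 3.29 and 60.4 ± 0.884 TPM (log2 -1.26) and ICAM1 stood at -0.87. NLRP3, SOD2, ZC3H12A, NFKBIE and IL1RN rose by log2 changes of 0.13 to 0.32.

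Monocyte and macrophage differentiation genes fell as a list (37 tested, 24 lower and 6 higher, also adjusted over the list alone, median log2 -0.33, camera adjusted p = 4.9e-05 and adjusted p = 0.111 with an estimated correlation). The median was -0.14 with no filter on low values or with a mean TPM of at least 5. CCR2, IRF8, THBD, S100A9, S100A8 and SPI1 rose. CEBPB, a monocytic transcription factor that is also on the stress list, fell by a log2 change of -1.89. The chemokine receptor CCR2 rose from 10.3 ± 0.615 to 33.8 ± 0.757 and 23.1 ± 2.20 TPM (log2 1.35), and the transcription factor IRF8 rose from 136 ± 0.813 to 241 ± 0.919 and 196 ± 0.863 TPM (log2 0.67). The granulocyte list had 5 tested members, 4 lower and 1 higher (also adjusted over the list alone, camera adjusted p = 0.045 and adjusted p = 0.258 with an estimated correlation), and its call was lost with no filter on low values, median-ratio scaling, no ribosomal protein genes, the replicate number as a block or no variance trend (adjusted p from 0.055 to 0.140, median log2 from -0.58 to -0.51, and -0.014 with no filter), and its median was -0.19 with a pseudocount of 5. Its calcium-binding protein S100P fell from 227 ± 4.61 to 24.7 ± 3.10 and 29.3 ± 1.43 TPM (log2 -3.03, adjusted p = 1.8e-13), CSF3R (-0.62), CEBPE (-0.51) and GFI1 (-0.15) fell and CXCR2 (0.67) rose. Progenitor markers went both ways (9 higher and 6 lower of 15, camera adjusted p = 0.55): the granule genes PRTN3 rose (0.70) and MPO fell (-0.47). The MLL-AF9 and HOXA leukaemia list was not called (6 higher and 7 lower of 25, camera adjusted p = 0.37), although FLT3, a receptor kinase, fell from 1812 ± 16.4 to 1330 ± 43.6 and 1417 ± 39.0 TPM (log2 -0.40) and LMO2 fell (-0.51). The MHC list, of whose 23 members 10 were matched to the table used and 8 were tested, was not called either (1 higher and 4 lower, camera adjusted p = 0.16), with CD74 at -0.59, HLA-E at -0.42, B2M at -0.21, HLA-C at -0.18 and TAP1 at 0.21.

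Of the cell cycle and survival lists, G2/M and mitosis rose slightly (47 tested, 25 higher and 6 lower, 25 and 7 adjusted over the list alone, median log2 0.10, camera adjusted p = 0.0033 and adjusted p = 0.591 with an estimated correlation). BUB1 (0.58), CDC20 (0.49) and CKS2 (0.48) rose. Against the list, CDC25C (-0.35), CKAP2L (-0.25), CKAP2 (-0.21), NUF2 (-0.18), NDC80 (-0.14) and TTK (-0.12) fell. The G1/S and DNA replication list was not called (14 higher and 13 lower of 46, camera adjusted p = 0.75), with CDT1 at -0.67 and PRIM1 at -0.60. Targets of p53 fell (25 tested, 12 lower and 6 higher, 13 and 6 adjusted over the list alone, median log2 -0.11, camera adjusted p = 0.026 and adjusted p = 0.169 with an estimated correlation, and 0.086 with no filter on low values). The median was -0.17 without sgNS replicate 1 and -0.19 without ribosomal protein genes. The latter setting dropped genes by symbol and so also left out RPS27L, a member of this list that rose. Of the members that fell, the stress cytokine GDF15 went from 21.0 ± 0.679 to 3.30 ± 0.474 and 1.16 ± 0.184 TPM (log2 -2.85), followed by BBC3 (-1.35) and the death receptor TNFRSF10B (-0.96). TRIAP1, TIGAR, AEN, RPS27L, POLH and RRM2B rose (0.18 to 0.40). The mean log2 change of the p53 list was -0.31, lower than its median. Whether this fall is separate from that of the integrated stress response list was not tested. Apoptosis regulators were not called (7 higher and 9 lower of 25, camera adjusted p = 0.55), PMAIP1 being lower by a log2 change of -0.96.

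In metabolism, the cholesterol synthesis list rose (26 tested, 17 higher and 5 lower, also adjusted over the list alone, median log2 0.25, camera adjusted p = 0.012 and adjusted p = 0.162 with an estimated correlation). With sgMETTL1.3 alone that list was not called (median log2 0.13, and 0.078 after median-ratio scaling and 0.081 without ribosomal protein genes, camera adjusted p = 0.56), and with sgMETTL1.6 alone it was (0.36, camera adjusted p = 1.7e-06 and adjusted p = 0.080 with an estimated correlation). SQLE, the squalene epoxidase, rose by a log2 change of 0.54. SREBF2 (-0.33), FDPS (-0.22), STARD4 (-0.19) and INSIG1 (-0.12) fell, and SCD, which desaturates fatty acids, fell from 449 ± 8.03 to 212 ± 2.05 and 349 ± 1.94 TPM (log2 -0.72). Hypoxia genes did not pass (3 higher and 8 lower of 15, median log2 -0.13, camera adjusted p = 0.052) but passed without sgNS replicate 2 (median -0.22, adjusted p = 0.037) and without sgMETTL1.6 replicate 1 (median -0.16, adjusted p = 0.040). VEGFA fell on that list from 212 ± 7.69 to 62.7 ± 0.643 and 38.4 ± 0.396 TPM (log2 -2.09) and MXI1 fell (-0.54), while HILPDA (0.33), BNIP3 (0.31) and ALKBH5 (0.29) rose. Glycolysis was not called (12 higher and 6 lower of 24, camera adjusted p = 0.22), with the glucose transporter SLC2A3 at -1.41 and GPI at 0.41. Autophagy and lysosome genes were not called (7 higher and 12 lower of 36, camera adjusted p = 0.11, and 0.042 after quantile normalization), with MAP1LC3B at -0.57 and SQSTM1 at -0.39. The oxidative stress list was not called over both guides (7 higher and 4 lower of 20, camera adjusted p = 0.75), its cystine transporter SLC7A11 at a log2 change of -2.05 and the ferritin light chain FTL at 0.20. MAFG (-0.26), ME1 (-0.20) and FTH1 (-0.090) also fell. The m6A machinery (7 higher and 2 lower of 20, camera adjusted p = 0.37), with HNRNPA2B1 at 0.32, IGF2BP3 at -0.45 and CBLL1 at -0.17, was not called. Replication-dependent histones (5 higher and 6 lower of 33, camera adjusted p = 0.90) were not called either. HIST1H3A (0.85), HIST1H4C (0.66), HIST1H2AH (0.64), HIST1H4J (0.60) and HIST1H3B (0.57) rose, and HIST1H2BK (-0.24) was 1 of the 6 that fell. Near-identical histone genes can share reads. The oxidative stress median was 0.015 with a mean of -0.042, and the G1/S list (0.011 and -0.016) likewise had a median and a mean of different sign. After median-ratio scaling these medians were -0.011 and -0.015, without ribosomal protein genes -0.015 and -0.019, and that of G1/S was -0.0062 after quantile normalization. Adjusted over the list alone, the counts of these 14 lists that did not pass were the same except for translation factors (15 higher, 17 lower), the unfolded protein response (12 and 12), G1/S (13 and 13) and histones (5 and 4).

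Genes that flank METTL1 on chromosome 12 went both ways (5 higher and 5 lower of 12, camera adjusted p = 0.55, median log2 0.017 and mean -0.015). METTL21B (0.46), AGAP2 (0.28), MARCH9 (0.25), CYP27B1 (0.24) and PIP4K2C (0.21) were higher, and CTDSP2 (-0.61), DTX3 (-0.42), TSPAN31 (-0.27), CDK4 (-0.18) and OS9 (-0.17) were lower.

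Among the highest rises over both guides were several genes outside the lists. The Wnt ligand WNT7B went from 2.30 ± 0.431 to 11.6 ± 0.0707 and 9.01 ± 0.919 TPM (log2 1.77, adjusted p = 1.6e-09) and EPAS1, which encodes HIF-2 alpha, from 2.34 ± 0.0283 to 13.6 ± 1.10 and 6.73 ± 0.495 TPM (log2 1.67). ADAMTS1, a secreted protease, rose by a log2 change of 1.58, the sepiapterin reductase SPR by 1.32, the fatty acid oxidation enzyme CPT1A by 1.13, the complement factor C3 by 1.11, the nucleotide receptor P2RY2 by 1.09, the oxysterol receptor GPR183 by 1.09 and the hyaluronidase HYAL2 by 1.06. SMN2 had the most negative log2 change, -4.01 (adjusted p = 0.00048), but its control libraries held 15.25 and 69.14 TPM, and its reads can be shared with the near-identical SMN1, so it is uncertain.

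Marker lists of other cell types had too few expressed genes to test. The T and NK cell list had 2, of which NKG7 fell from 118 ± 7.13 to 91.3 ± 3.92 and 94.4 ± 2.75 TPM (log2 -0.34, adjusted p = 1.5e-05). The B cell list had 2, with EBF1 at no more than 4.99 TPM in any library, and the epithelial and fibroblast list 3, of which KRT18 fell from 16.3 TPM to 12.04 ± 0.785 and 12.7 ± 0.106 TPM (log2 -0.38). The erythroid and megakaryocyte list had 2. Its transferrin receptor TFRC, which dividing cells of many types express, rose from 240 ± 4.36 to 457 ± 17.8 and 454 ± 22.2 TPM (log2 0.92, adjusted p = 1.4e-10). Mitochondrially encoded mRNAs are not analysed here.

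Each guide was then compared with the control on its own. The changes were closely alike across genes, with Pearson r = 0.887 over 10911 genes, which are not independent replicates. Both comparisons use the same control libraries, which alone makes their changes alike. In 100 simulations all 3 groups, controls included, were drawn unchanged, and the mean r was 0.50. Each gene and library varied independently there. A deviation common to both control libraries could not arise, so the simulated values do not weigh against one. The observed covariance was 0.104 against a simulated 0.0025. The libraries labelled sgMETTL1.3 differed from control at 6385 genes (3743 higher, 2642 lower) and those labelled sgMETTL1.6 at 5563 (2801 higher, 2762 lower). These majorities turned with median-ratio scaling (3055 higher and 3205 lower, and 2745 and 2810) and without ribosomal protein genes (3081 and 3119, and 2614 and 2907). That of sgMETTL1.6 also turned with no filter on low values (2382 and 2548), without the variance trend (2589 and 2591) and without sgNS replicate 1 (2100 and 2166). Of the 30 lists, 15 and 17 passed camera and none passed with an estimated correlation. Of the 16 lists called over both guides, cholesterol synthesis (adjusted p = 0.56), G2/M and granulocyte markers (0.0504 each) were not called with sgMETTL1.3, but the last 2 were called without sgNS replicate 1, sgMETTL1.3 replicate 2 or either sgMETTL1.6 library (adjusted p from 0.020 to 0.046). Targets of p53 were not called with sgMETTL1.6 (median log2 -0.086, adjusted p = 0.054), but were called without ribosomal protein genes or without any 1 of the sgNS and sgMETTL1.6 libraries (adjusted p from 0.035 to 0.049, median from -0.21 to -0.089), and after quantile normalization their median was -0.028 (adjusted p = 0.080). The setting without ribosomal protein genes also left out RPS27L of the p53 list. With sgMETTL1.3 the median of the p53 targets of -0.19 was -0.12 without its replicate 2. The NF-kB list was called lower with sgMETTL1.3 (median log2 -0.039, adjusted p = 0.034), but not after median-ratio scaling (-0.087, adjusted p = 0.057). Its median was -0.17 without ribosomal protein genes, -0.076 after quantile normalization, and -0.087, -0.067 and -0.074 without sgNS replicate 1, sgNS replicate 2 and sgMETTL1.3 replicate 2. The tRNA modification call with sgMETTL1.6 (adjusted p = 0.047) was lost without sgNS replicate 1 or sgMETTL1.6 replicate 1 (0.054 each). The MHC list, not called with sgMETTL1.6 (adjusted p = 0.070), was called lower after quantile normalization (0.040) and without sgMETTL1.6 replicate 2 (0.045). Hypoxia genes were called lower with sgMETTL1.3 (adjusted p = 0.035 and adjusted p = 0.196 with an estimated correlation) but not after median-ratio scaling (adjusted p = 0.059), and autophagy and lysosome genes with sgMETTL1.6 (adjusted p = 0.0045 and adjusted p = 0.188 with an estimated correlation). The test of the difference between the guides was not passed by granulocyte markers (adjusted p = 0.88), hypoxia genes (0.48) or p53 targets (0.41). Both guides called 4446 genes in the same direction, 2416 higher and 2030 lower, and 65 in opposite directions. Independent lists of these sizes would share 961 and 669, and no simulation called more than 1 gene higher or 2 lower with both. A split of the controls, chosen after seeing the data, leaves 1 control library for each guide. Both are sgNS libraries, so a deviation common to them would remain, and the split cannot weigh against one. With sgNS replicate 2 as the control of sgMETTL1.3 and replicate 1 as that of sgMETTL1.6, r was 0.868 and the covariance 0.103, and 1971 genes were called higher and 1589 lower with both, against 643 and 425 for independent lists. With the controls exchanged, r was 0.814 and the covariance 0.0992, and 1689 and 1423 genes were called with both, against 637 and 447. The integrated stress response list fell with each guide, 35 of 36 members lower at a median log2 of -1.61 with sgMETTL1.3 (camera, adjusted p = 5.6e-32 and adjusted p = 0.112 with an estimated correlation) and 35 of 36 at -1.82 with sgMETTL1.6 (adjusted p = 1.4e-35 and adjusted p = 0.080 with an estimated correlation). Heat shock chaperones rose with each, 17 of 19 at a median log2 of 0.62 (adjusted p = 1.3e-09 and adjusted p = 0.112 with an estimated correlation) and 16 of 19 at 0.55 (adjusted p = 3.4e-12 and adjusted p = 0.080 with an estimated correlation). With sgMETTL1.3 the log2 changes most negative among the named genes were those of CHAC1 (-3.58), S100P (-3.15), SMN2 (-3.06), CTH (-2.92) and PSAT1 (-2.66), and the most positive those of EPAS1 (2.13), WNT7B (1.94), C3 (1.92), CCR2 (1.62) and ADAMTS1 (1.62). With sgMETTL1.6 they were those of SMN2 (-4.95), CHAC1 (-4.08), GDF15 (-3.35), CTH (-3.07) and S100P (-2.91), and of WNT7B (1.61), ADAMTS1 (1.54), HSPA8 (1.51), SPR (1.23) and EPAS1 (1.21). The SMN2 call with sgMETTL1.3 was lost without sgNS replicate 2 (log2 -2.005, adjusted p = 0.099), without sgMETTL1.3 replicate 2 (log2 -1.15, adjusted p = 0.079), with no filter on low values (adjusted p = 0.128) and without the variance trend (adjusted p = 0.066). Without sgMETTL1.3 replicate 1 its log2 change was -4.97.

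**Figure D3:**
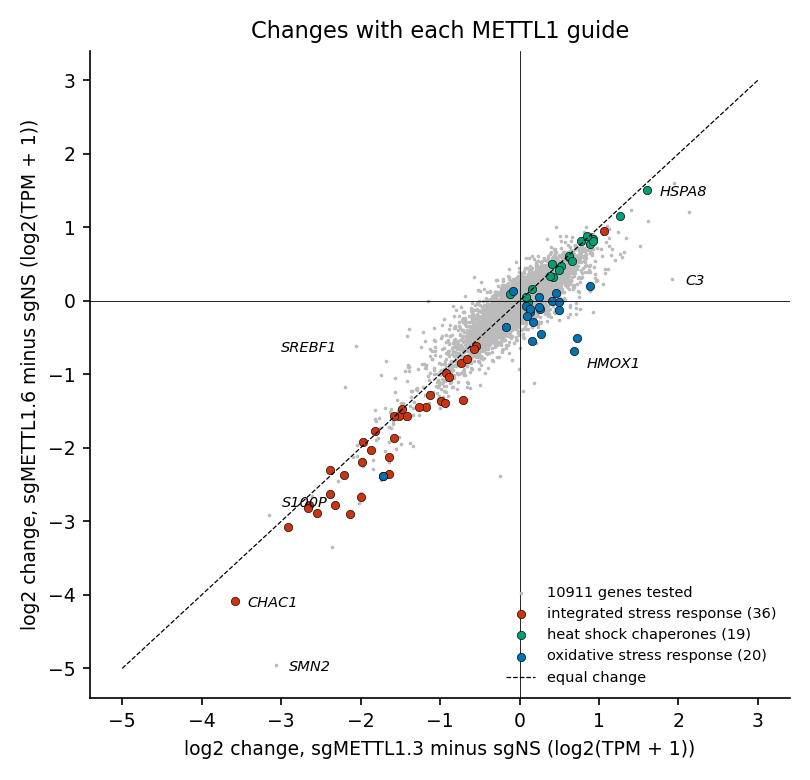
Log2 change on the log2(TPM + 1) scale with sgMETTL1.3 (horizontal axis) and sgMETTL1.6 (vertical axis) against sgNS for 10911 genes, with 3 gene lists coloured and the dashed line marking equal change. The points follow the dashed line (r = 0.887), with integrated stress response genes at the lower left and most oxidative stress genes below the line.

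Last, the guides were compared with each other. Oxidative stress genes, the targets of NRF2, moved in opposite directions. They rose with sgMETTL1.3 (13 higher and 2 lower of 20, median log2 0.24, camera adjusted p = 0.0081 and adjusted p = 0.144 with an estimated correlation) and fell with sgMETTL1.6 (2 higher and 11 lower, median log2 -0.12, camera adjusted p = 0.0055 and adjusted p = 0.128 with an estimated correlation). Between the guides 18 of the 20 were lower with sgMETTL1.6 and 1, TXN, was higher (19 and 1 adjusted over the list alone, median difference -0.39, camera adjusted p = 1.6e-14 and adjusted p = 0.048 with an estimated correlation). The haem oxygenase HMOX1 stood at 13.9 ± 1.17 TPM in the controls, 22.9 ± 0.156 TPM with sgMETTL1.3 and 8.37 ± 1.72 TPM with sgMETTL1.6 (difference -1.36, adjusted p = 2.4e-06). FTL stood at 6691 ± 106, 8868 ± 195 and 6682 ± 215 TPM (difference -0.41, adjusted p = 6.6e-07). Cholesterol synthesis genes were higher with sgMETTL1.6 than with sgMETTL1.3 (18 higher and none lower of 26, 19 and none adjusted over the list alone, median difference 0.20, camera adjusted p = 3.2e-18 and adjusted p = 0.048 with an estimated correlation). The lipid regulator SREBF1 was at 38.6 ± 1.84 TPM in the controls, 8.53 ± 0.714 TPM with sgMETTL1.3 and 24.8 ± 0.325 TPM with sgMETTL1.6 (difference 1.44, adjusted p = 3.9e-08). The cholesterol exporter ABCA1 was at 5.85 ± 0.106, 0.50 ± 0.00707 and 2.03 ± 0.0919 TPM (difference 1.02, adjusted p = 2.5e-05).

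In total 2510 genes differed between the guides, 789 of them (31.4%) higher with sgMETTL1.6 and 1721 lower. That split depended on the scaling: 972 were higher and 803 lower after quantile normalization (54.8% higher), 1102 and 810 after median-ratio scaling (57.6%), and 932 and 959 without ribosomal protein genes (49.3%). The count fell to 1274 without sgMETTL1.3 replicate 1, to 1215 without its replicate 2 and to 1446 without sgMETTL1.6 replicate 1, each of which leaves a guide with 1 library. It was 1023 with no filter on low values and 1409 without the variance trend. Of the 30 lists 11 differed by camera, 6 higher and 5 lower with sgMETTL1.6, of which the oxidative stress and cholesterol lists also passed with an estimated correlation. Cytosolic ribosomal proteins were higher with sgMETTL1.6 (56 higher and none lower of 76, 62 and none adjusted over the list alone, median difference 0.13, camera adjusted p = 8.7e-38 and adjusted p = 0.073 with an estimated correlation). That median was 0.075 after a trend on GC content and length was removed. The integrated stress response list was lower still with sgMETTL1.6 (21 lower and none higher of 36, 23 and none adjusted over the list alone, median difference -0.16, camera adjusted p = 1.5e-08 and adjusted p = 0.184 with an estimated correlation). Immediate early genes were less reduced with it (12 higher and 2 lower of 24, median difference 0.13, camera adjusted p = 6.1e-07 and adjusted p = 0.184 with an estimated correlation). The members lower over all genes tested were IER3 (-0.65) and KLF10 (-0.24), and adjusted over the list alone 13 were higher and 3 lower. The medians of the other 6 lists were as follows: aminoacyl-tRNA synthetases -0.12 (none higher, 12 lower), autophagy -0.11 (none, 15), ribosome biogenesis -0.085 (1, 12), the MLL-AF9 list 0.061 (4, none), oxidative phosphorylation 0.038 (14, 1) and G2/M 0.022 (10, 2), with adjusted p from 0.184 to 0.591 with an estimated correlation. Adjusted over the list alone their counts were 0 and 16, 2 and 18, 1 and 13, 3 and 0, 14 and 2, and 10 and 2. Members against these lists were GAR1 (0.21, ribosome biogenesis), NDUFV1 (-0.15, oxidative phosphorylation) and ANLN and MKI67 (-0.16 each, G2/M), and the MLL-AF9 list members higher over all genes tested, of which the first 3 were chosen after their values were seen, were CCNA1 (0.29), BCL2 (0.22), HOXA9 (0.16) and FLT3 (0.091). After median-ratio scaling the medians of these 6 lists were -0.077 (7 lower), -0.068 (13 lower), -0.039 (6 lower), 0.11, 0.084 and 0.067 in the same order. The MLL-AF9 and G2/M medians were also over 1.5 times higher after quantile normalization (0.11 and 0.065) and without ribosomal protein genes (0.094 and 0.055), autophagy was at -0.065 after quantile normalization, and ribosome biogenesis and oxidative phosphorylation were at -0.051 and 0.072 without ribosomal protein genes. Oxidative phosphorylation was at 0.014 without sgMETTL1.6 replicate 2. G2/M was not called without sgMETTL1.6 replicate 1 (median -0.0040, adjusted p = 0.162), and its median was 0.078 without sgMETTL1.6 replicate 2 and 0.057 and 0.010 without sgMETTL1.3 replicates 1 and 2. C3 (difference -1.62) and RGS16 (-1.27) were lower with sgMETTL1.6, and ROPN1L (1.15), FAM69C (1.02) and TMEM135 (0.93) were higher. HIST1H4K held 7.56 and 0 TPM with sgMETTL1.6 against 12.57 and 11.3 TPM with sgMETTL1.3, and its call (difference -2.14, adjusted p = 0.028) was lost without either sgMETTL1.3 library (adjusted p = 0.095 and 0.075), with no filter on low values (0.220), without the variance trend (0.132) and after quantile (0.081) or median-ratio scaling (0.061). The difference was -0.59 without sgMETTL1.6 replicate 2 and -3.69 without its replicate 1. Near-identical H4 genes can share its reads.

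**Figure D4:**
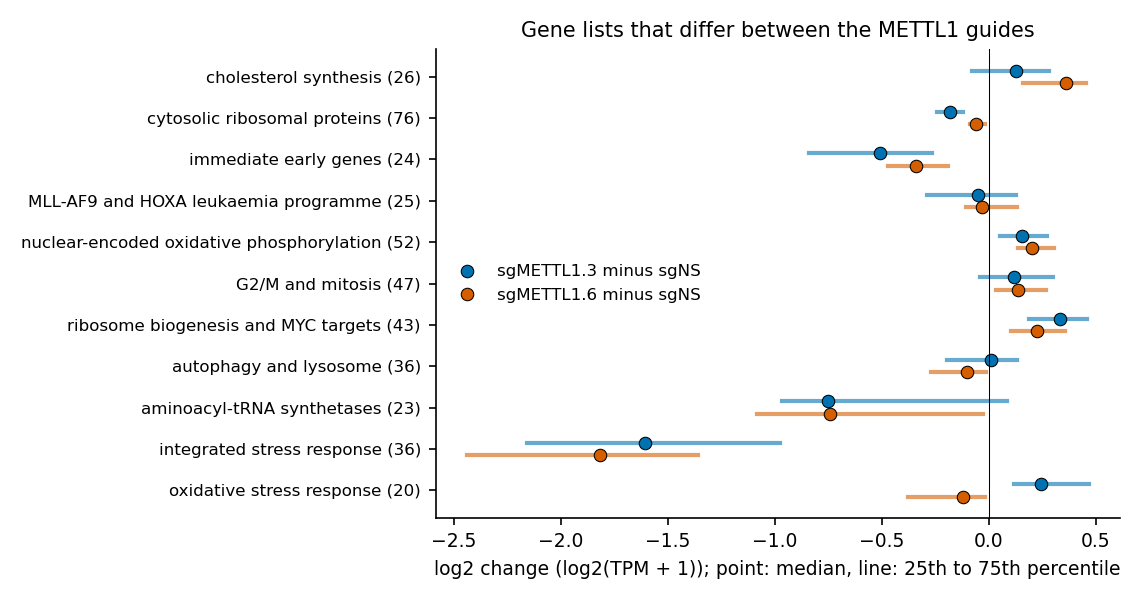
Median log2 change (points) and 25th to 75th percentile of the members (lines) on the log2(TPM + 1) scale with sgMETTL1.3 (blue) and sgMETTL1.6 (orange) against sgNS for the 11 lists that differ between the guides, with the number of tested members in brackets. The oxidative stress list lies at 0.24 with sgMETTL1.3 and -0.12 with sgMETTL1.6, on either side of 0.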

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

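The tests of endoplasmic reticulum stress, culture state, one response at 2 strengths and SMN read splitting were chosen only after the result was seen, as were the interval of the ribosomal protein test and the median-ratio value of the strengths test.

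The guides differed at 2510 genes by a test of the difference itself. The ribosomal protein list (0.13), cholesterol synthesis (0.20), immediate early genes (0.13), the MLL-AF9 list (0.061), oxidative phosphorylation (0.038) and G2/M (0.022) had higher medians with sgMETTL1.6. The oxidative stress list (-0.39), the integrated stress response (-0.16), aminoacyl-tRNA synthetases (-0.12), autophagy (-0.11) and ribosome biogenesis (-0.085) had lower ones. Of these lists, only oxidative stress and cholesterol synthesis also passed camera with an estimated correlation. The G2/M median was -0.0040 without sgMETTL1.6 replicate 1. METTL1 itself differed by -0.57.

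Among named genes, those lower with sgMETTL1.6 by the same test included GDF15 (-0.99) of the p53 list. They also included the integrated stress response members STC2 (-0.76), SLC7A11 (-0.66), CHAC1 (-0.50), CEBPB (-0.49), SESN2 (-0.46), ALDH1L2 (-0.33), PSAT1 (-0.16) and ASNS (-0.13), and the synthetases WARS (-0.26), SARS (-0.21) and GARS (-0.12). Others lower were HIST1H4K (-2.14), C3 (-1.62), HMOX1 (-1.36), RGS16 (-1.27), EPAS1 (-0.92), CPT1A (-0.77), VEGFA (-0.69), IER3 (-0.65), CCR2 (-0.54), P2RY2 (-0.49), PRTN3 (-0.49), SQSTM1 (-0.43), FTL (-0.41), CXCR2 (-0.41), MX1 (-0.36), WNT7B (-0.34), CSF3R (-0.32), XAF1 (-0.32), GPR183 (-0.30), IRF8 (-0.30), HERPUD1 (-0.28), SRM (-0.25), CXCL8 (-0.25), HIST1H2BK (-0.17), GPI (-0.16), LTV1 (-0.14), HSP90AA1 (-0.11), PSMD2 (-0.11) and HSPA8 (-0.089). Higher with sgMETTL1.6 were SREBF1 (1.44), ROPN1L (1.15), ABCA1 (1.02), FAM69C (1.02), TMEM135 (0.93), SCD (0.72), FOS (0.50), DUSP1 (0.48), XBP1 (0.43), SLC2A3 (0.34), CKS2 (0.25), RPL31 (0.24), S100P (0.24), MPO (0.22), SQLE (0.17) and FLT3 (0.091). The HIST1H4K call was lost without either sgMETTL1.3 library (adjusted p = 0.095 and 0.075).

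The difference between the guides was weighed against 3 explanations. Scaling of the libraries is argued against as the whole cause, since at least 1775 genes differed under each of 3 other scalings. One response at 2 strengths is argued against too: of 1013 genes called in the same direction with both guides that also differed, 739 were stronger with sgMETTL1.3 and 274 (27.0%) with sgMETTL1.6, and the smaller share was 30.2% of 768 genes after median-ratio scaling. A trend on GC content and length explained 11.5% of the variance of the difference, and without it the ribosomal protein median went from 0.13 to 0.075; the value meets the bound set in advance, but its interval of 0.061 to 0.094 reaches below that bound, so this stays open for that list. Differences between the guides in cutting, in off-target sites or between cultures were not tested and stay open.

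The lower integrated stress response list (median -1.76) was weighed next. Scaling is argued against by a median of -1.79 under the other scaling nearest to 0, and GC content and length by one of -1.76 after their trend was removed. Endoplasmic reticulum stress in the control cells cannot be told apart, because the chaperone and degradation genes of that organelle went both ways (median -0.037, 95% interval -0.11 to 0.13, 29 genes, and -0.064 after median-ratio scaling and -0.062 after quantile normalization). A culture state of the control cells, such as denser or more depleted medium, cannot be told apart either: the hypoxia median was -0.13 and the glycolysis median 0.099 with neither list called over both guides, but hypoxia was called without sgNS replicate 2 (median -0.22, adjusted p = 0.037), without sgMETTL1.6 replicate 1 (-0.16, 0.040) and with sgMETTL1.3 alone (0.035, and 0.059 after median-ratio scaling). Loss of METTL1 stays possible as a biological hypothesis, and with 1 control guide an effect of the control cells themselves may produce the same pattern.

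SMN2 (log2 -4.01) was weighed last. SMN1 held 164.27 and 111.74 TPM in the controls, 199.81 and 206.15 with sgMETTL1.3 and 214.33 and 211.85 with sgMETTL1.6, and the summed SMN1 and SMN2 TPM changed by a log2 ratio of 0.23 only. This is consistent with reads being assigned to one copy or the other, so no change of SMN2 itself is claimed.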

How the results depend on the processing

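Alternatives for lists between the guides, for lists with each guide, for the controls of each guide, for lists without members shared with the integrated stress response list and for symbol families were chosen after seeing the data; the others were fixed before the data were examined. Apart from the METTL1 change over both guides, 1837 of the named-gene values under the alternatives kept their direction and side of the threshold and 13 lost the call. Of the list values over both guides 440 kept both, 12 lost the call, 3 gained it and 23 medians close to 0 changed sign with no call on either side; the cause was not tested. The G1/S median (0.011) became -0.0062 after quantile normalization, -0.015 after median-ratio scaling and -0.019 without ribosomal protein genes, and the oxidative stress median (0.015) -0.011 and -0.015 under the last 2 of these. The histone median (-0.00030) became 0.0086 and 0.0071 with pseudocounts of 0.1 and 5, 0.0037 with a mean TPM of at least 5 and 0.049 after quantile normalization. The median of the METTL1 neighbours (0.017) became -0.029 with no filter on low values, -0.033 with a mean TPM of at least 5, -0.0088 after median-ratio scaling and -0.013 without ribosomal protein genes. When 1 library was left out, medians ranged from -0.025 to 0.0068 (translation factors), -0.060 to 0.0051 (unfolded protein response), -0.031 to 0.027 (G1/S), -0.081 to 0.12 (histones) and -0.033 to 0.053 (METTL1 neighbours). No scaling moved the median of all genes by over 0.1. The number of genes that differed between the guides was 1023 with no filter on low values, which tests more genes, and 1409 with limma without the trend; it ranged from 1215 to 2476 when 1 library was left out, with 1274 and 1215 without sgMETTL1.3 replicates 1 and 2 and 1446 without sgMETTL1.6 replicate 1. A group left with 1 library is assumed to vary like the others. Requiring a log2 change of at least 1 left 159 genes over both guides. Of the 30 lists, 0 passed with an estimated correlation, 10 with a preset correlation of 0.05 (lost were tRNA modification, G2/M, p53 targets, granulocyte markers, NF-kB and cholesterol synthesis) and 25 with fry, which does not compare a list with other genes. The METTL1 log2 change over both guides reversed to 0.022 without sgNS replicate 1 and ranged from -0.12 to 0.022; neither value passed, and the cause was not tested. Leaving out 1 library gave 4962 to 6458 genes over both guides, 5117 to 6609 with sgMETTL1.3 and 4266 to 5486 with sgMETTL1.6. Under the 3 other scalings and without each library in turn, 2 list calls were lost and 8 gained with sgMETTL1.3, 2 and 7 with sgMETTL1.6, and 1 and 7 between the guides. The 11 lists that differed between the guides kept their calls under the 3 other scalings, in which the ribosomal list was left out of one; G2/M lost its call without sgMETTL1.6 replicate 1. The monocyte and macrophage list, not called between the guides (adjusted p = 0.067), was called lower with sgMETTL1.6 after median-ratio scaling (0.042), quantile normalization (0.024) and without ribosomal protein genes (0.046), and without sgMETTL1.3 replicate 2 or either sgMETTL1.6 library; glycolysis gained one after quantile normalization (0.0012). Without CARS, which the integrated stress response list shares, the synthetase median was -0.69 (camera, adjusted p = 9.9e-06), and without CEBPB the monocyte median was -0.31 (adjusted p = 0.00017). Only symbols on both lists were removed, so this cannot tell whether either fall is separate from that of the stress response. Depth is unknown, so no limit from depth can be stated.

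With the replicate block, a paired fit on the replicate number, the counts were 6976 over both guides, 6916 with sgMETTL1.3, 6175 with sgMETTL1.6 and 3615 between the guides, with 15 lists over both guides. Same-numbered libraries deviated with correlations of -0.0050 (sgNS and sgMETTL1.3), 0.21 (sgNS and sgMETTL1.6) and 0.15 (sgMETTL1.3 and sgMETTL1.6). Each count of genes was higher with the block, so a deviation that same-numbered libraries share stays possible. The labels do not say what the replicate number stands for. With the block the granulocyte list lost its call over both guides (camera, adjusted p = 0.055). The other 29 lists over both guides, the 30 lists in each of the other 3 comparisons and the named-gene values kept their side of the threshold.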

Other observations

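The scan of gene families by symbol, and its tests under other scalings, were chosen only after the result was seen; the codon test was written before.

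Families of genes sharing a symbol stem were scanned over both guides, mostly outside the fixed lists. Of 167 families with at least 8 tested genes, 4 passed camera, and 0 passed with an estimated correlation (adjusted p = 0.997 for each of the 4). Proteins of the large mitochondrial ribosomal subunit (MRPL) rose, 35 higher and 3 lower of 46 at a median log2 of 0.22 (adjusted p = 8.7e-05), and those of the small subunit (MRPS) too, 20 higher and 3 lower of 28 at 0.18 (adjusted p = 0.0038). MRPS6 went from 112 ± 4.14 TPM in the controls to 200.1 ± 2.93 TPM with sgMETTL1.3 and 173 ± 3.51 TPM with sgMETTL1.6 (SD over both libraries of each group), and MRPL12 from 330 ± 5.52 to 454 ± 12.6 and 440 ± 8.73 TPM, whereas MRPL33 fell (log2 -0.25). The ribosomal RNA processing family (RRP) rose, 7 higher and none lower of 8 at 0.33 (adjusted p = 0.028); RRP9 (0.38) and RRP12 are on the ribosome biogenesis list, so it is not independent of that list.

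The ATF family fell, 8 lower and none higher of 9 at a median log2 of -0.29 (adjusted p = 0.0011); it includes ATF3 (log2 -1.18), ATF4 (-0.58) and ATF5 (-1.03), which are on the integrated stress response list, so it is not independent of that list. Medians after median-ratio scaling were 0.20 (MRPL), 0.15 (MRPS), 0.31 (RRP) and -0.32 (ATF), each still past camera.

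One hypothesis was that mRNAs rich in the arginine codon AGA, which is read by a tRNA that METTL1 is known to methylate, changed level. Across 9523 genes, which are not independent replicates, the rank correlation of the log2 change over both guides with the AGA share of arginine codons was -0.14, and -0.025 (95% bootstrap interval -0.043 to -0.0048) given GC content at the third codon positions and length. The bound set in advance for no relation was a size under 0.05, which this value meets, so mRNA levels give little support to the hypothesis; translation is not measured by these data.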
